A study of Rattus norvegicus with 6 samples.

How the data were processed

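Renal cortex RNA of 6 rats, 3 given corn oil and 3 given phenylbutazone, was measured on one-colour Agilent expression arrays, 1 array per animal. Per the series design the 3 samples of a group are biological replicates. Per the labels' protocols, RNA was labelled with the dye Cy3 after linear amplification. Per the submitters' processing notes and the file headers, images were read with Agilent Feature Extraction 10.7. The deposited scanner files hold the processed signal of each spot as an intensity on a linear scale, background-subtracted and detrended inside Feature Extraction, with small values replaced by a positive surrogate, and, per the file headers, not normalized between arrays. The deposited value table of the series holds a ratio per probe: set against the scanner values of the same array it was the processed intensity divided by that array's 75th percentile, with medians of 0.110, 0.110 and 0.109 on vehicle arrays 1, 2 and 3 and 0.105, 0.106 and 0.107 on phenylbutazone arrays 1, 2 and 3, and its 61605 rows included all 61537 non-control probes. Scale, centring and direction of that table are therefore settled. The probe layout names the rat genome build rn4, and no coordinates are given here.

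Each array held 62976 spots, of which 1439 were controls and were left out. Another 40 probes with an outlier flag on any array were left out, and no spot was saturated. Intensities were taken to log2 and each array's 75th percentile was subtracted. Probes well above background on at least 3 of the 6 arrays were kept, 41006 (66.6%), and 20491 dim probes were not tested. The files identify probes by accession rather than by gene symbol. Accessions without version were matched to a table of RefSeq genes of the assembly GRCr8, used for names only, which named 28206 of 61537 probes (45.8%). The other probes kept the accession of the file. A gene was represented by its probe with the highest mean level, giving 29938 genes, 12155 with a symbol and 17783 without. Among 64 further probes of the genes tabulated by name, 11 had the opposite sign, among them probes of Cx3cl1, Cdkn1a, Cyp4a2, Actg2, Mki67 and Slc22a6.

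Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, on log2 values, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors after ± are standard errors of the log2 difference. Where a gene was well above background on no array of a group, the difference is given as a bound: the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the probe's own value and the lowest value well above background on that array. Gene lists of kidney segments, other cell types, drug metabolism, stress and injury, 38 in all with 1144 entries, were tested with camera at a preset correlation of 0.01, wherever at least 4 members were measured. The estimated correlation and fry were alternatives. Median differences of the 6 called lists were the same to 2 decimals with dim members set at their bound.

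The groups, the gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined. The rule took, among genes with a current symbol whose groups lay fully apart, the 12 with the largest difference in each direction among those past the threshold, filled up with those of smallest p, together with up to 4 members of a list past the threshold and 17 fixed genes. As no gene passed, the 24 genes of smallest p were named as not having passed, and the list members named beside them were chosen after their values were seen. Some genes the rule names are not reported here. Alternatives were scaling to the median, normexp background correction with an offset of 50, quantile normalization, the deposited ratio values, no filter or a stricter filter on dim probes, every probe on its own, an intensity trend, slide as a fixed or random block, slide 2 alone, the replicate number as a block, and leaving out each replicate. On slide 2 alone the single vehicle array is assumed to vary like the phenylbutazone arrays. The erythrocyte marker score as a covariate was added after seeing the data. The scan day divides the arrays exactly as the slide does. Normexp was run on the median spot intensity, since the design had named the mean spot intensity, which was not used here.

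The fit was tested on simulated data for the comparison of phenylbutazone with vehicle, with 29938 genes, assumed independent between arrays. Each gene's spread was the eBayes estimate from the real arrays, which is drawn toward a value common to all genes. The recovery therefore holds for such spreads rather than for each gene's own. Of 100 genes changed 2-fold 53% were recovered, and of 100 changed 4-fold 93%, with 8 false calls among the other genes. A list of NRF2 targets shifted by 0.5 log2 units was called, with 0 other lists called by camera. With no change simulated, limma called 1 gene and 5.00% of the genes had an unadjusted p under 0.05. The simulation holds no slide effect and says nothing about one.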

Results

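Total RNA of the renal cortex, the outer kidney layer that holds the glomeruli and most proximal tubules, was profiled in 6 male Sprague-Dawley rats. Of these, 3 animals received corn oil as the vehicle and 3 received phenylbutazone, a non-steroidal anti-inflammatory drug that inhibits the cyclooxygenases encoded by Ptgs1 and Ptgs2, at 200 mg/kg/day for 4 weeks. Each animal's RNA was hybridised to its own one-colour array of 61537 non-control probes. Between 65.2% and 68.4% of the probes on an array were well above background, and the 75th percentile of the processed intensity lay between 891 and 1003. Vehicle arrays 1 and 2 shared slide 1, whereas vehicle array 3 and the 3 phenylbutazone arrays shared slide 2, which was scanned on another day. The number of arrays, 3 per group, limits the precision of every comparison.

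Over the 29938 genes tested, the first principal component (29.4% of the variance) placed vehicle arrays 1 and 2 at -41.2 and -36.3 and vehicle array 3 at 52.3, with the phenylbutazone arrays between them, the highest at 18.9. The second component (25.7%) placed the 3 vehicle arrays at 20.0 to 40.5 and the 3 phenylbutazone arrays at -39.8 to -12.1.

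**Figure D1:**
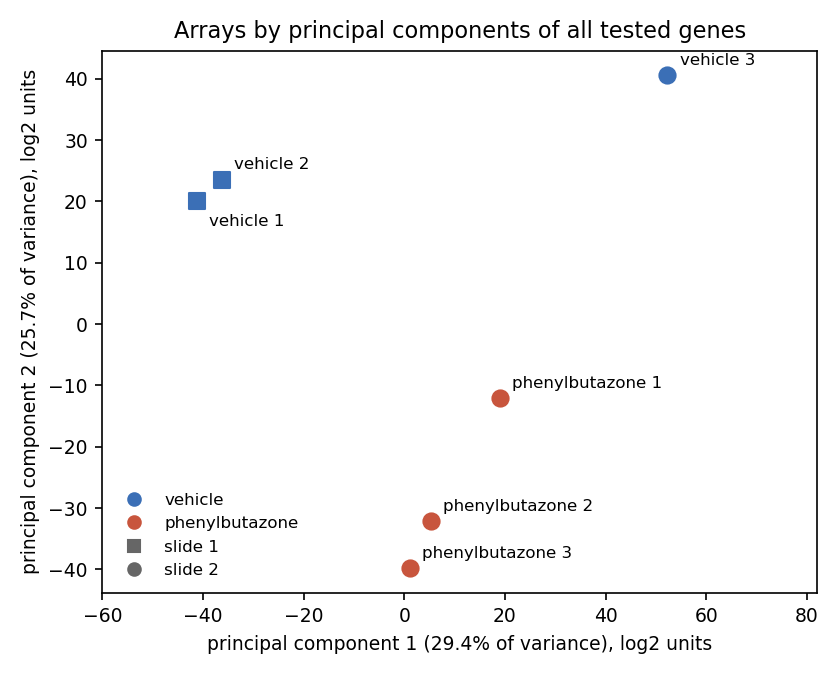
Scores of the 6 arrays on the first (x axis) and second (y axis) principal components of the log2 levels of all tested genes. Colour gives the group and shape the slide; vehicle 3 lies at 52.3 on the first component, away from vehicle 1 and 2 at -41.2 and -36.3, and the groups lie apart on the second.

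The comparison of phenylbutazone with vehicle asks which transcripts of the renal cortex differ after 4 weeks of dosing. Vtcn1, which encodes the immune checkpoint ligand B7-H4, was at least 5.56-fold higher in the phenylbutazone group, with a limma adjusted p of 0.0648; it was not well above background on any vehicle array, so that only a bound can be given. Acsbg1, which encodes an acyl-CoA synthetase, stood at -1.63 ± 0.11 log2 units (SE, n = 3 per group), 3.09-fold lower, with a limma adjusted p of 0.0648. Cish, a cytokine-induced inhibitor of STAT5 signalling, stood at -1.86 ± 0.18 (3.63-fold lower), and Igfbp4, which encodes an insulin-like growth factor binding protein, at -1.29 ± 0.19 (2.45-fold lower), with limma adjusted p values of 0.115 and 0.164. Against the single vehicle array of slide 2, which is also the value with slide as a fixed block, the differences were -1.76 for Acsbg1, -2.05 for Cish and -1.58 for Igfbp4.

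None of these genes passed the test, and neither did any other. Under alternatives Vtcn1 passed with slide as a random block (limma adjusted p = 0.0290), quantile normalization (0.0116) and an intensity trend (0.0424), in a range of 0.0116 to 0.461 over all alternatives. Acsbg1 passed with normexp (0.0227) and the trend (0.0271), in a range of 0.0161 to 0.461, and Cish with the trend (0.0465), in a range of 0.0286 to 0.461. All 3 also passed without vehicle replicate 3, at 0.0149 for Vtcn1 and at the lowest value of their range for Acsbg1 and Cish. In that setting treatment and slide divide the arrays in the same way, so it cannot separate phenylbutazone from slide or scan day. With limma and Benjamini-Hochberg adjustment, 0 of the 29938 genes had an adjusted p under 0.05, and so 0 passed with a difference of at least 2-fold. At an unadjusted p under 0.05 there were 3657 genes (1788 higher and 1869 lower in phenylbutazone) where 1496.9 would be expected by chance, and limma with an intensity trend called 8. In 6446 genes, 21.5% of those tested, all values of one group lay above all values of the other, against a chance share of 10%. Among these, 147 were at least 2-fold higher in phenylbutazone and 149 at least 2-fold lower. Both chance values assume arrays without a slide effect. Divisions that mixed the treatments but kept vehicle 1 and 2, the arrays of slide 1, together gave 1711 to 2171 genes at an unadjusted p under 0.05 (limma). With slide as a fixed block limma called 0 genes at an adjusted p under 0.05 and 9461 at an unadjusted p under 0.05. The lowest limma adjusted p in that setting was 0.0594, shared by Vtcn1, Acsbg1, Cish and Igfbp4, so the 0 fell just short of the threshold. That setting rests on vehicle 3 as the only vehicle array of slide 2. The count of genes passing depended on a single array, since without vehicle replicate 3, where treatment and slide coincide, limma called 814 genes, 237 higher and 577 lower.

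The 24 genes taken by the rule for the smallest p, 12 in each direction, had limma adjusted p values of 0.0648 to 0.189 and none passed. On the higher side stood the glutamate transporter gene Slc1a3 at 1.75 ± 0.24 log2 units and Npffr2, which encodes a neuropeptide FF receptor, at 1.21 ± 0.13. Gls2, which encodes a glutaminase, stood at 0.98 ± 0.13, and Proc, which encodes the anticoagulant zymogen protein C, at 0.82 ± 0.10. Car15, which encodes a carbonic anhydrase, stood at 0.92 ± 0.12 and Insrr, which encodes the alkali-sensing insulin receptor-related receptor, at 0.85 ± 0.10. The ribonuclease gene Rnase4 at 0.74 ± 0.098 and Bltp3b at 0.64 ± 0.089 followed, while Or9k2 was at least 3.80-fold and Usp51 at least 1.38-fold higher, with neither well above background on any vehicle array. On the lower side stood Ihh, which encodes the secreted signal Indian hedgehog, at -1.01 ± 0.13, and Sdr42e1 at -1.03 ± 0.16. Mmp28, which encodes a matrix metalloproteinase, stood at -0.86 ± 0.13 and Tcf15, which encodes a transcription factor, at -0.77 ± 0.12. Smaller differences were those of Wscd2 (-0.77 ± 0.12), C1ql4 (-0.75 ± 0.11), Gabrq (-0.66 ± 0.10), Hspb9 (-0.61 ± 0.098) and Mrgprf (-0.59 ± 0.089). At least 1 other probe of the same gene stood much nearer to 0 for Insrr (0.26), Bltp3b (0.0054), Proc (0.41), Ihh (-0.21), Tcf15 (-0.20), Mrgprf (-0.24) and Wscd2 (-0.054), the value nearest 0 being given.

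**Figure D2:**
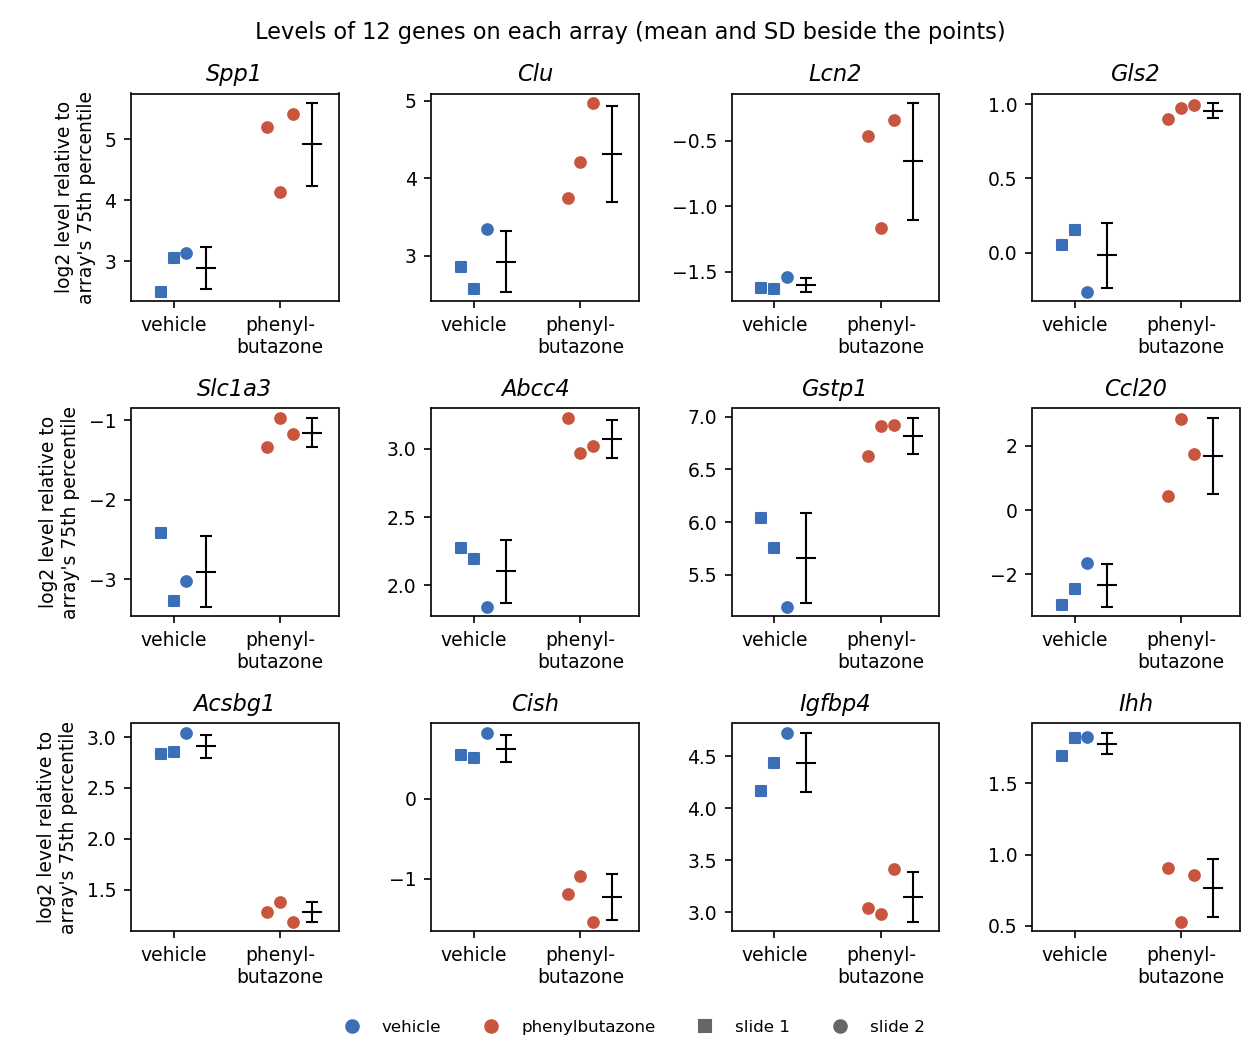
Log2 level relative to the array's 75th percentile (y axis) on each of the 6 arrays for 12 genes, with the mean and SD of each group (n = 3) beside its points. Colour gives the group and shape the slide; in each of the 12 genes all values of one group lie above all values of the other, and 0 of the 12 had a limma adjusted p under 0.05.

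Among the genes fixed in advance, the injury markers osteopontin (Spp1), clusterin (Clu) and lipocalin 2 (Lcn2) were 2.02 ± 0.36, 1.39 ± 0.35 and 0.94 ± 0.22 log2 units higher in phenylbutazone, with higher values in 3 of 3 treated animals than in any vehicle animal. Havcr1, which encodes the tubular injury marker Kim-1, differed by -0.19 ± 0.47. Ptgs2, the inducible cyclooxygenase gene, was well above background on 1 of 3 phenylbutazone arrays and on 3 of 3 vehicle arrays, so that its difference of -1.68 ± 0.71 is uncertain. Ptgs1, the constitutive one, stood at -0.22 ± 0.15. Of the 17 fixed genes 14 were tested, and 0 passed over all genes (limma), while 3 passed adjusted over the list alone, namely Spp1 (adjusted p = 0.0179), Clu (0.0325) and Lcn2 (0.0325), which were also the 3 with an unadjusted p under 0.05. Over all genes the limma adjusted p values of these 3 were 0.208, 0.285 and 0.275. With slide as a block 0 of the 14 passed over the list alone, at adjusted p values of 0.387, 0.408 and 0.396 for Spp1, Clu and Lcn2. The antioxidant genes Nqo1 (0.29 ± 0.20) and Hmox1 (-0.57 ± 1.11), the cell cycle genes Cdkn1a (-0.050 ± 0.12) and Mki67 (0.0071 ± 0.26), the fatty acid hydroxylase gene Cyp4a2 (0.011 ± 0.090) and the organic anion transporter genes Slc22a6 (0.10 ± 0.089) and Slc22a8 (-0.029 ± 0.11) differed by less than 2 standard errors. Cyp2b1, Cyp3a9 and Cyp1a1, the drug-inducible cytochrome genes of the set, were well above background on 0 of 6 arrays and were not tested.

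Of the 38 gene lists, 6 were called higher in phenylbutazone and 0 lower by camera with a preset correlation of 0.01, and 0 were called with an estimated correlation. Members are given below with log2 differences and SE at n = 3 per group, and 0 members of any list passed over all genes. In 6 of the 10 divisions of the 6 arrays into 3 and 3, the real one included, camera called at least 6 lists, and the highest count in another division was 12.

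The 33 measured kidney injury markers had a median log2 difference of 0.39, with 28 members higher and 5 lower (camera adjusted p = 3.60e-05, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone 9 members passed, all higher, against 0 over all genes: Spp1, Clu, Lcn2, the keratin gene Krt18 (1.41 ± 0.41), the cornified envelope gene Sprr1a (0.99 ± 0.27), the galectin gene Lgals3 (0.72 ± 0.16), the calcium-binding protein genes S100a6 (0.55 ± 0.12) and Anxa2 (0.39 ± 0.093) and the metalloproteinase inhibitor gene Timp1 (0.47 ± 0.11). Within slide 2 the median was 0.72 (camera adjusted p = 0.0320), and with slide as a block the adjusted p was 0.0300. The median of the kidney injury markers was 0.60 without phenylbutazone replicate 1 and 0.27 without phenylbutazone replicate 3, and over all alternatives their adjusted p lay between 3.28e-08 and 0.985. The score of the list, the mean deviation of its members from their own means, was -0.45, -0.22 and -0.083 in vehicle 3, 1 and 2 and -0.094, 0.21 and 0.64 in phenylbutazone 1, 2 and 3. Erythrocyte markers were higher in the same group, with a lowest score of -0.47 in vehicle 3 and a highest of 0.50 in phenylbutazone 3, but stood at 0.29 and -0.16 in phenylbutazone 1 and 2, in the opposite order. Of the injury markers 2 passed adjusted over the list alone with slide as a block. This setting and slide 2 alone rest on vehicle 3 as the only vehicle array of slide 2. That array had the lowest injury score.

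The 35 measured targets of the oxidative stress regulator NRF2 had a median of 0.29, with 31 members higher and 4 lower (camera adjusted p = 3.60e-05, adjusted p = 0.200 with an estimated correlation). Adjusted over the list alone 3 members passed, against 0 over all genes: the efflux transporter gene Abcc4 (0.97 ± 0.15) and the glutathione transferase genes Gstp1 (1.16 ± 0.23) and Gstm1 (0.96 ± 0.20), the last uncertain because of near-identical paralogs. With slide as a block 2 of the NRF2 targets passed over the list alone. Gclc, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, stood at 0.17 ± 0.83. NRF2 targets were the only list for which fry, which tests whether members move one way on balance, gave an adjusted p under 0.05 (0.00134). The fry test does not compare the list with other genes. The call for NRF2 targets was lost with slide as a block (median 0.34, adjusted p = 0.147) and within slide 2 (adjusted p = 0.0919), in a range of 8.00e-09 to 0.200 over all alternatives. The NRF2 list scores were 0.13 to 0.19 in phenylbutazone and -0.22 to -0.080 in vehicle, and the erythrocyte markers were higher in the same group (median 0.47).

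The 27 measured genes of the cholesterol biosynthesis list had a median of 0.22, with 24 members higher and 3 lower (camera adjusted p = 6.09e-05, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone 1 member passed, against 0 over all genes: Insig1 (0.67 ± 0.11), which encodes a protein that holds back SREBP processing when sterols are present. Other Insig1 probes stood lower, at 0.33, 0.39 and 0.44. With slide as a block 11 members of the cholesterol list passed over the list alone. In that setting 9461 of the 29938 genes tested had an unadjusted p under 0.05, so many genes outside the list moved too. It rests on vehicle 3, the only vehicle array of slide 2, which had the lowest cholesterol score, -0.30. Sqle, which encodes squalene epoxidase, stood at 0.39 ± 0.10, and another Sqle probe at 0.18. Within slide 2 the median was 0.29 (camera adjusted p = 0.00895), and with slide as a block the adjusted p was 0.00843, in a range of 3.14e-07 to 0.985 over all alternatives for cholesterol biosynthesis. Erythrocyte markers moved with this list too, at a median of 0.47.

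The 14 measured erythrocyte markers had a median of 0.47, with 12 members higher and 2 lower (camera adjusted p = 0.00461, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone 1 member passed, against 0 over all genes and 0 with slide as a block. The globin genes Hba-a1 (0.44 ± 0.22) and Hbb-b1 (0.55 ± 0.23), near-identical to other globin genes, did not pass. Within slide 2 the median was 0.63 (camera adjusted p = 0.0476), but the erythrocyte call was lost with slide as a block (adjusted p = 0.0867) and without vehicle replicate 3 (median 0.40, adjusted p = 0.146), in a range of 1.73e-06 to 0.985 over all alternatives for the erythrocyte markers. The score in phenylbutazone 2, -0.16, lay within the range of the vehicle arrays, -0.47 to -0.064.

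The 28 measured inflammatory cytokines and NF-kB targets had a median of 0.25, with 19 members higher and 9 lower (camera adjusted p = 0.0473, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone 1 member passed, against 0 over all genes and 0 with slide as a block: Ccl20 (4.02 ± 0.64, 16.2-fold higher), which encodes the chemokine ligand of the receptor Ccr6. The chemokine gene Cxcl10 stood at 0.89 ± 0.31 and the neutrophil chemoattractant gene Cxcl1 at 1.14 ± 0.44, whereas the macrophage chemokine gene Ccl4 stood at -0.62 ± 0.21. Within slide 2 the median was 0.47 (camera adjusted p = 0.0366). The call for inflammatory cytokines and NF-kB targets was lost with slide as a block (adjusted p = 0.0784) and without vehicle replicate 1 (median 0.19, adjusted p = 0.0807), vehicle replicate 3 (0.13, 0.583), phenylbutazone replicate 2 (0.21, 0.0672) or phenylbutazone replicate 3 (0.093, 0.170). It held in 9 of 21 alternatives (adjusted p 0.00098 to 0.985). Erythrocyte markers were higher in the same group (median 0.47).

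The 44 measured PPAR alpha targets and genes of fatty acid oxidation had a median of 0.13, with 33 members higher and 11 lower (camera adjusted p = 0.0473, adjusted p = 0.985 with an estimated correlation). Adjusted over the list alone 0 members passed (limma), as over all genes, with 6 at an unadjusted p under 0.05. The mitochondrial carnitine palmitoyltransferase gene Cpt2 stood at 0.51 ± 0.12 and the peroxisomal thiolase genes Acaa1b and Acaa1a, which are close paralogs, at 0.65 ± 0.18 and 0.48 ± 0.17, whereas Cyp4a3 stood at -0.73 ± 0.33. For PPAR alpha targets and fatty acid oxidation the call was lost with slide as a block (median 0.060, adjusted p = 0.866), where camera's direction was down although the median stayed above 0, and within slide 2 (adjusted p = 0.916). It was also lost without vehicle replicate 1 (median 0.15, adjusted p = 0.255), vehicle replicate 2 (0.10, 0.238), phenylbutazone replicate 2 (0.073, 0.510) or phenylbutazone replicate 3 (0.054, 0.236). Without phenylbutazone replicate 1 the median was 0.25. The PPAR alpha call held in 9 of 21 alternatives (adjusted p 1.47e-05 to 0.985). Erythrocyte markers were higher in the same group (median 0.47).

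**Figure D3:**
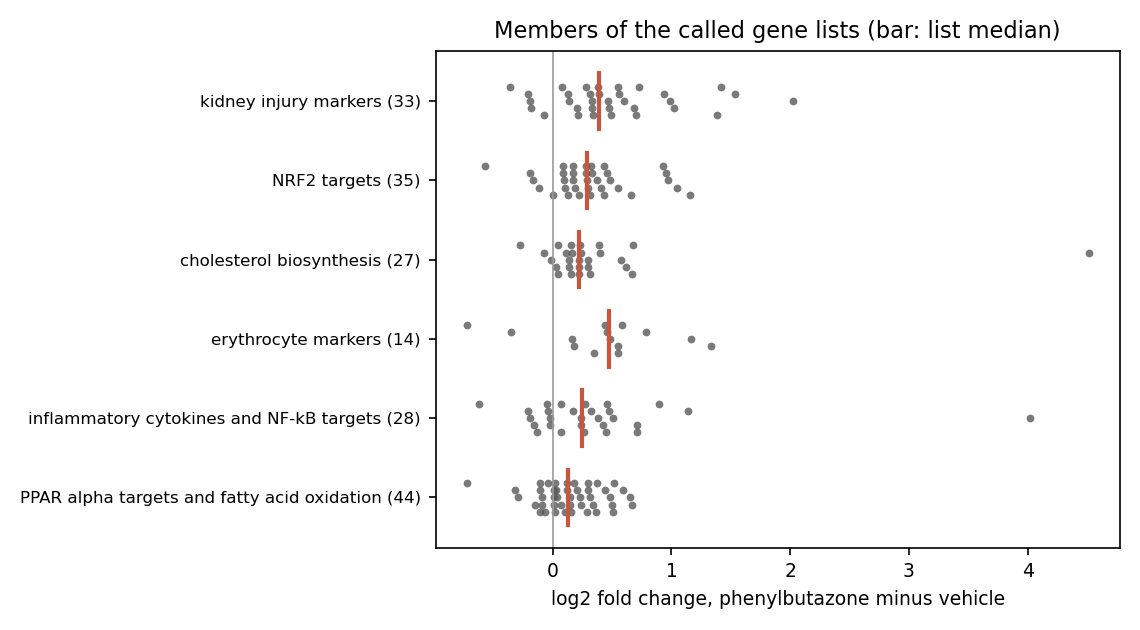
Log2 difference between phenylbutazone and vehicle (x axis) of each measured member of the 6 gene lists called by camera, with the number of members in brackets; the bar is the list's median. Medians lie between 0.13 and 0.47, and 0 single members passed the test over all genes.

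**Figure D4:**
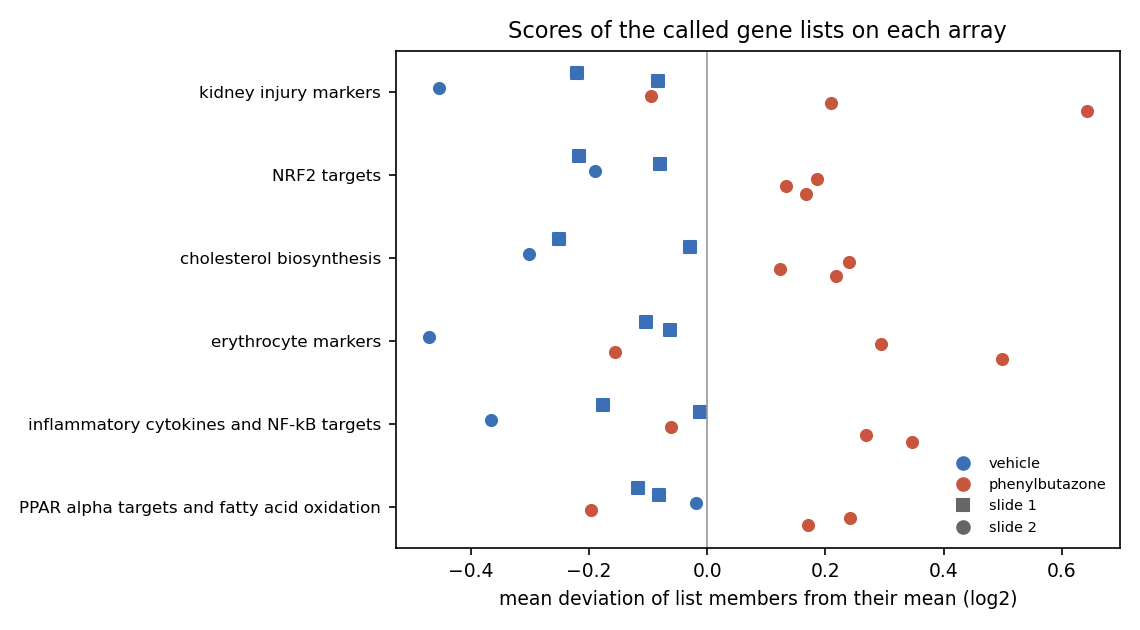
Score of the 6 called lists on each array (x axis, log2), the mean deviation of the members from their mean over the 6 arrays; colour gives the group and shape the slide. NRF2 targets and cholesterol genes separate the groups, whereas in each of the other 4 lists phenylbutazone 1 or phenylbutazone 2 lies below the highest vehicle array.

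The other 32 lists had camera adjusted p values of 0.253 to 0.958, and adjusted p values of 0.985 to 0.988 with an estimated correlation. Among nephron segments the medians were 0.056 for proximal tubule markers, 0.064 for thick ascending limb markers, -0.026 for distal convoluted and connecting tubule markers, 0.10 for principal cell markers, 0.12 for intercalated cell markers, 0.063 for renal medulla and papilla markers and -0.020 for podocyte markers. Among other cell types they were -0.097 for endothelial markers, 0.045 for smooth muscle, mesangial and pericyte markers, 0.12 for macrophage and myeloid markers, 0.069 for lymphocyte markers, 0.096 for MHC class II genes, 0.0063 for adipocyte markers and -0.028 for adrenal markers. The xenobiotic metabolism genes under CAR and PXR had a median of 0.13, the 5 measured AhR targets 0.22, organic ion and drug transporters 0.048 and prostanoid synthesis, transport and receptor genes 0.055. Medians of the metabolic lists were 0.079 for gluconeogenesis and ammonia production, 0.066 for lipid synthesis and storage, 0.0076 for the mitochondrial respiratory chain, 0.11 for vitamin D, calcium and phosphate handling and 0.0091 for aldosterone and sodium handling. Those of the stress and growth lists were 0.11 for p53 targets, 0.022 for hypoxia targets, 0.055 for the heat shock response, 0.037 for the endoplasmic reticulum and amino acid stress response, 0.024 for the interferon response, -0.025 for immediate early genes, -0.14 for proliferation and cell cycle genes (0.24 within slide 2, -0.33 without vehicle replicate 3), 0.045 for extracellular matrix genes and 0.028 for circadian clock genes.

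Some members of these 32 lists passed adjusted over the list alone, against 0 over all genes. They included the intercalated cell genes Insrr, Car15 and Slc26a4 (0.68 ± 0.18), the last encoding the anion exchanger pendrin. On the list of gluconeogenesis and ammonia production they were the glutaminase gene Gls2 and G6pc1 (0.50 ± 0.11). Abcc4 passed in both the prostanoid and the drug transporter list. In the smooth muscle list the contractile genes Actg2 (-1.21 ± 0.25) and Smtn (-0.46 ± 0.10) passed, but the other Actg2 probes stood at 0.21 and 0.026. No member of the other lists did. The counts differed with slide as a block, with 8 thick ascending limb markers, 7 hypoxia targets, 7 interferon response genes and 5 endothelial markers passing over their list alone. With slide as a block camera also called the endothelial markers lower (median -0.23, adjusted p = 0.0300) and the respiratory chain (0.16) and the interferon response (0.29) higher, both with an adjusted p of 0.0300, and within slide 2 the adjusted p values were 0.0320, 0.0455 and 0.0320. Both settings rest on vehicle 3 as the only vehicle array of slide 2, whose interferon response score was -0.25 against 0.12 and 0.17 in vehicle 1 and 2 and -0.10 to 0.050 in phenylbutazone. These calls describe that array as much as the treatment. Leaving out phenylbutazone replicate 1 made camera also call the lists of xenobiotic metabolism (median 0.17), organic ion and drug transporters (0.21), macrophage and myeloid markers (0.28) and lymphocyte markers (0.15) higher. Without phenylbutazone replicate 3 it called intercalated cell markers (0.13). On leaving out 1 replicate the median changed sign in 19 of these 32 lists, and that of the thick ascending limb markers ran from -0.20 without vehicle replicate 3 to 0.19 without vehicle replicate 2. The median of the AhR targets was -0.0029 without vehicle replicate 3 and 0.021 without phenylbutazone replicate 2. The sign of the median differed from that of the mean or of camera's direction for the circadian, adipocyte, immediate early, distal tubule, medulla, extracellular matrix and interferon lists, all with medians between -0.026 and 0.063.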

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

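The tests of the slide as a source, of a wrong label and with the erythrocyte covariate were chosen only after the result was seen. This includes those for single lists. The other divisions of the arrays were planned, as were slide as a fixed block and leaving out each replicate as settings of the main test.

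The spike-in transcripts of the labelling kit, which are added to the RNA and do not come from the animal, were a signal outside the genes compared. Relative to each array's 75th percentile, the 8 of 10 spike-in probes that were detected on all arrays lay 0.94 log2 units (median, range 0.57 to 1.01) higher on slide 2 than on slide 1. Vehicle array 3 differed from vehicle arrays 1 and 2 by 0.88, and the phenylbutazone arrays differed from vehicle array 3 by 0.022.

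Without vehicle replicate 3, the remaining vehicle arrays are all on slide 1 and the phenylbutazone arrays all on slide 2, and limma called 814 genes against 0 with all arrays. On a scale where the mean of vehicle 1 and 2 is 0 and that of phenylbutazone is 1, the median position of the left-out vehicle 3 over these genes was 0.97 (5th to 95th percentile -0.13 to 1.62; 66.6% of the genes above 0.75), which is consistent with slide or scan day as the source of most of the 814. In gene sets of the same size chosen without a phenylbutazone array, at least 14.5% of the genes had vehicle 3 below 0.25. For phenylbutazone arrays held out in the same way this share was 6.39% to 7.86%. Positions of vehicle 3 also spread more widely than theirs at both the 5th and the 95th percentile. Any more deviant array could give a larger share, so this test cannot decide whether vehicle 3 carries a wrong label. An effect of phenylbutazone may remain among the 12.9% of the 814 genes with vehicle 3 below 0.25, and a difference of the animal itself was not separated from its slide.

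For the lists called higher in phenylbutazone, in 5 of the 6 called lists, all but the PPAR alpha list, the score of vehicle 3 lay below every phenylbutazone array of the same slide, and with slide as a block camera still called kidney injury markers (median 0.72 against 0.39) and cholesterol biosynthesis (0.29 against 0.22). Set against the spread between arrays, 0 of the 6 list scores passed with slide as a block (adjusted p = 0.0776 for cholesterol biosynthesis and NRF2 targets and 0.169 for kidney injury markers), so that slide or scan day stays open, with 1 vehicle array on slide 2. With the erythrocyte score as a covariate, 4 of the 5 other called lists were still called by camera at the preset correlation, just the number set as the criterion. That criterion refers to the called lists, so it was written once they were known. The lower quartile stayed above 0 only for the 2 lists of NRF2 targets (median 0.30, quartiles 0.048 and 0.60) and PPAR alpha targets (0.18, 0.082 and 0.48). The quartile criterion was set after the values were seen, and the score itself differs between the groups. More erythrocytes thus stay open as a source of these 2 lists. The median was smaller for injury markers (0.19 against 0.39, quartiles -0.14 and 0.52 against 0.20 and 0.70) and cholesterol genes (0.15 against 0.22, -0.0012 and 0.28 against 0.12 and 0.35). Both were still called by camera (adjusted p = 0.0218 and 0.0245). It was also smaller for the inflammatory list (0.12 against 0.25, -0.22 and 0.34 against -0.026 and 0.46), whose call ended with the covariate (camera adjusted p = 0.434). As the score differs between the groups, a smaller median cannot show whether erythrocytes are the source, which stays open for these 3 lists. The most abundant erythrocyte markers Hba-a1, Hbb-b1 and Hbb stood at 0.44, 0.55 and 0.46, the erythrocyte member Slc4a1 is also on the intercalated cell list, and phenylbutazone itself stays open as a biological source.

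The 6 arrays make 10 divisions into 3 and 3, too few for a share under 0.05. The counts in the real division and the highest in another were 0 and 2 for genes passing, 0 and 2 for those passing at 2-fold or more, 0 and 0 for fixed genes, 3657 and 2171 for genes at an unadjusted p under 0.05, and 6 and 12 for gene lists called, with 6 lists also where vehicle 1 and 2 were grouped with phenylbutazone 1 or phenylbutazone 3. The numbers of divisions with a count as large, the real one included, were 10, 10, 10, 1 and 6 of 10. The 3 highest counts of genes at an unadjusted p under 0.05 outside the real division were those that kept vehicle 1 and 2, the arrays of slide 1, together, at 1711 to 2171, against 559 to 1093 in the others.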

How the results depend on the processing

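The erythrocyte covariate was an alternative chosen after seeing the data, and all others were planned. The count of genes passing, 0 in the report, was 2 with normexp, 1 with quantile normalization, 8 (3 higher, 5 lower) with an intensity trend and 1 with slide as a random block, and the same numbers passed at 2-fold or more. It was 0 with median scaling, the deposited ratios, either filter, every probe, slide or scan day as a fixed block, slide 2 alone and the erythrocyte covariate. Leaving out 1 replicate gave 0 to 814 genes, and 0 to 260 at 2-fold or more, the highest without vehicle replicate 3, with 1 without vehicle replicate 2 or phenylbutazone replicate 3 and 2 without phenylbutazone replicate 2. The replicate block gave 0 genes, 0 at 2-fold or more, 0 fixed genes and 6 lists, and the numbers did not pair the samples (correlations of same-numbered deviations -0.074 to 0.011, and 0 of 3 matched best by number). Fixed genes passing stayed at 0 in every setting. The 6 lists called became 0 with an estimated correlation and 1 (NRF2 targets) with fry, 4 to 10 on leaving out 1 replicate, the highest without phenylbutazone replicate 1, and 4 to 7 elsewhere. In 6 settings 1 list was called lower: the respiratory chain with quantile normalization (median -0.084), endothelial markers with slide as a block and within slide 2, and proliferation and cell cycle with the erythrocyte covariate (-0.44), without vehicle replicate 3 (-0.33) and without phenylbutazone replicate 3 (-0.21). Camera's direction for PPAR alpha targets and fatty acid oxidation turned down with slide as a block and within slide 2 (median 0.060 in both). Camera compares a list with the other genes, and the median of all genes was 0.055 in both settings, against 0.015 in the main fit. Whether this turned the direction was not tested. The fixed genes changed sign in 37 of 265 values under alternatives; the 24 genes of smallest p, chosen with groups fully apart, could not on leaving out arrays. Median scaling shifted the median of all genes from 0.015 to 0.063. Signal over background limits what can be said of dim genes, as 65.2% to 68.4% of the probes of an array were well above it.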

Other observations

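The genes in this part were chosen after their values were seen, and none passed limma's test over all genes with all 6 arrays.

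Kng1 and Kng2, which encode kininogens, the precursors of kinins, stood at 2.91 ± 0.52 and 2.85 ± 0.52 log2 units in phenylbutazone against vehicle (SE, n = 3 per group). They are close paralogs, and a shared signal of their probes was not tested. Both were higher in 18 of 18 other settings, at 2.37 to 3.74 for Kng1 and 2.27 to 3.69 for Kng2. These settings re-use the arrays on which the genes were chosen, so the shared direction is no independent evidence. Serpina3n, which encodes a serine protease inhibitor of the acute phase, stood at 2.86 ± 0.60, and Bcl6, which encodes a transcriptional repressor, at 2.27 ± 0.43. Igfbp1 stood at 1.60 ± 0.40 and Igfbp4, in the other direction, at -1.29 ± 0.19.

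Beside the chemokine Ccl20, its receptor gene Ccr6 stood at 1.60 ± 0.28. Fcgr2b (1.36 ± 0.39) and Spib (1.01 ± 0.40), which B cells express, were on the same side, while the lymphocyte list was not called with all arrays (median 0.069, camera adjusted p = 0.253). Fcgr2b is also on the macrophage and myeloid list, which was not called either (median 0.12, camera adjusted p = 0.449), so it does not mark B cells alone. The epithelial integrin genes Itgb4 and Itgb6 stood at 0.66 ± 0.11 and 0.81 ± 0.15. The apical calcium channel genes Trpv5 and Trpv6 stood at 1.12 ± 0.28 and 1.46 ± 0.52. The tight junction genes Cldn22 (-1.67 ± 0.27) and Cldn24 (-1.47 ± 0.38) were on the lower side.

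Gal, which encodes the neuropeptide galanin, was at 4.81 on vehicle array 2, beside values above 3 on each phenylbutazone array and -5.00 and -4.74 on vehicle arrays 1 and 3. With all arrays the difference of Gal was 5.59 ± 2.61, with a limma adjusted p of 0.452. Without vehicle replicate 2 it was 8.82 with a limma adjusted p of 0.0164. That setting removes the only vehicle array at the treated level, and Gal was picked after its values were seen. The smaller p is therefore no evidence of a difference. Hmox1 was at 2.76 on the same vehicle array, beside -1.55 and -1.09 on vehicle arrays 1 and 3 and -0.89 to -0.32 on the phenylbutazone arrays.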
